A study of Homo sapiens with 12 samples.

How the data were processed

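Gene expression was measured in MCF7, an established human breast cancer cell line that expresses the estrogen receptor. Cells were transfected with a control siRNA or with an siRNA against CtBP and were then kept in normoxia or in hypoxia. CtBP stands for C-terminal binding protein, a transcriptional corepressor encoded by the paralogs CTBP1 and CTBP2 that binds NADH. The 4 groups (control siRNA normoxia, control siRNA hypoxia, CtBP siRNA normoxia and CtBP siRNA hypoxia) held 3 arrays each, 12 in all, and per the labels the 3 replicates of a group were separately transfected batches. The medium was DMEM with 25 mM glucose, and total RNA was taken at subconfluence with a column kit that included a DNase step. The oxygen level, the time in hypoxia, the siRNA sequence and whether it was made against CTBP1, CTBP2 or both were not used here.

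Biotin-labelled RNA was hybridised to 1-colour Affymetrix-type gene arrays. The authors normalized the arrays with RMA, which corrects background, sets all arrays to a shared distribution and summarises the probes of a gene into a single value. The deposited values were on a linear intensity scale, from 2.54 to 13353, so log2 was taken before any test. The version of the authors' RMA software was not used here. No genome build was named, so no coordinates are given. An array has no read depth, and the number of arrays limits the precision.

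Of 32321 probes, 19158 had exactly 1 gene symbol, 1388 had several and 11775 were not listed with a gene. Of the probes with 1 symbol, 19128 were found by gene number in a current gene table, and 0 symbols changed. The probe with the highest mean over all 12 arrays stood for each gene, which left 18404 genes. Several probes were present for 637 genes. No filter was set on dim genes.

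Tests were run in R 4.3.3 with limma 3.58.1. All 12 arrays entered a single fit of 4 group means (lmFit and eBayes, two-sided, 8 residual and 14 total degrees of freedom). Contrasts were the knockdown in normoxia, the knockdown in hypoxia, hypoxia with control siRNA, hypoxia with CtBP siRNA, the difference between the knockdown effects (interaction), and both effects averaged over the other factor. A positive value means higher with CtBP siRNA, or higher in hypoxia. P-values were adjusted by Benjamini-Hochberg over all genes within a contrast, with a threshold of 0.05. Values given as "±" are standard errors of the log2 fold change from limma, except for group means, where the SD over 3 arrays is given. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

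Whether replicate numbers pair the arrays was checked from the correlation between the deviations of same-numbered arrays from their group means, across genes, with a minimum of 0.1 in each of the 3 numbers. In the knockdown contrasts r was 0.284, 0.148 and 0.223 in normoxia and 0.2, 0.267 and 0.14 in hypoxia, so the numbers paired the arrays there, and 6 of 6 arrays correlated best with the array of their own number. Counts from a fit with the replicate number as a block are therefore given beside those of the knockdown contrasts.

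The choice of tests, threshold, gene lists and alternatives was made before the data were examined. There were 22 gene lists with 445 members, of which 402 were measured. They covered HIF targets of glycolysis, other HIF targets, DNA replication, mitosis, p53 targets, estrogen receptor targets, epithelial and mesenchymal genes, fibroblast, basal breast and immune markers, pro-apoptotic BH3 and CtBP-linked death genes, and the interferon response. They also covered the integrated stress response, endoplasmic reticulum chaperones, cholesterol synthesis, oxidative phosphorylation, CtBP complex partners, Wnt, Notch and NF-kB targets, and reference genes. HIF is the hypoxia-inducible transcription factor. Lists were tested with camera (limma) with a preset correlation of 0.01, adjusted over the 22 lists of a contrast, and again with the correlation estimated from the arrays.

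The genes named were fixed by a rule. CTBP1 and CTBP2 were always named. In each single contrast the rule took up to 12 genes with the largest rise and 12 with the largest fall among those past the threshold whose 3 arrays of a group all lay above the 3 of the other, leaving out unnamed transcripts. Where no gene passed in the interaction, it took the 3 with the smallest p. From each list it took up to 4 members past the threshold with the largest change and up to 2 of the brightest that did not pass, and for overlaps up to 5 genes per direction. The use of the rule for the averaged contrasts was decided after their values had been seen.

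Alternatives were the replicate block, quantile normalization again, centring of each array on its median, leaving dim genes out, the mean over a gene's probes, all probes as features, a trended and robust prior, array weights, a fit to the 6 arrays of a contrast alone, a minimum log2 change of 1, and leaving out each array in turn. The block without the first control siRNA hypoxia array was added after the data had been seen. Tested on simulated data with 200 changed genes among 18404, the fit recovered between 27.1% and 31.8% of changes of 0.5 on the log2 scale and at least 95.2% of changes of 1 in the 4 single contrasts. In the interaction it recovered 10.8% of changes of 0.5 and 76.5% of changes of 1, with 7.6% false calls. The simulated noise was independent between genes and arrays, without replicate effects or an array that stands apart. The simulated knockdown in normoxia had 151 calls, against 4 in the real data, which makes the adjusted threshold easier to pass. Recovery in the real data may therefore be lower. Probes without a single gene name were left out of the gene tests.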

Results

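Genome-wide transcript levels of MCF7 cells were measured on 12 arrays in a 2-factor design, with CtBP knockdown by siRNA as the first factor and hypoxia as the second. Each of the 4 groups held 3 arrays from separately transfected batches. CtBP proteins repress transcription together with histone-modifying enzymes and bind NADH, so the design asks how much of the expression program of hypoxic cells depends on them. The median intensity per array lay between 17.8 and 19.2, and arrays of a group correlated with r from 0.976 to 0.993 across genes. The first principal component, with 41.9% of the variance, parted hypoxia from normoxia. The first control siRNA hypoxia array stood apart. Its median r with the other arrays was 0.965, against at least 0.978 for the others, and its weight from limma was 0.299, against at least 0.829 for the others. Some of the results below are also given without it. Where a list lost its call and no other median is given, its median stayed within 1.5 times that of the full fit.

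The first question was whether CTBP1 and CTBP2, the genes that encode CtBP, were measured at lower levels. Whether the siRNA was made against both of them is not used here. In normoxia CTBP1 averaged 5.67 ± 0.30 (log2 intensity, SD, n = 3) with control siRNA and 5.23 ± 0.01 with CtBP siRNA. The log2 fold change was -0.44 ± 0.14 (95% interval -0.74 to -0.13, limma unadjusted p = 0.00878) and did not pass over all genes (adjusted p = 0.579, or 0.452 with the replicate block), although CTBP1 was lower in 3 of 3 replicate pairs. In hypoxia CTBP1 averaged 5.43 ± 0.11 and 5.25 ± 0.16, a log2 fold change of -0.18 (adjusted p = 0.65) with 3 of 3 pairs lower, which lay between -0.23 and -0.09 over the alternatives and leave-outs. The brighter CTBP2 probe gave log2 fold changes of -0.26 ± 0.26 in normoxia (adjusted p = 0.986) and 0.00 ± 0.26 in hypoxia (adjusted p = 0.998), lower in 2 of 3 pairs each time. The value in hypoxia rested on the first control siRNA hypoxia array (4.84, against 6.05 and 6.02 on the other 2), and without it the change was -0.40 (adjusted p = 0.373). Over the alternatives and leave-outs CTBP2 lay between -0.36 and -0.09 in normoxia and between -0.40 and 0.20 in hypoxia. The other CTBP2 probe gave 0.08 and 0.04. Averaged over oxygen conditions, CTBP1 changed by -0.31 ± 0.10 (95% interval -0.52 to -0.09, limma unadjusted p = 0.00888, adjusted p = 0.187). Adjusted over the 3 probes of both genes alone, a choice made after the values had been seen, CTBP1 passed in normoxia (adjusted p = 0.0263, or 0.0363 with the replicate block) and on average (0.0266, or 0.0366 with the block). Over all genes the arrays did not call a lower transcript level for either gene. On single arrays the CTBP1 values did not overlap between the siRNAs, with 5.33 to 5.91 against 5.22 to 5.24 in normoxia and 5.36 to 5.56 against 5.07 to 5.34 in hypoxia, while those of CTBP2 did.

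**Figure D1:**
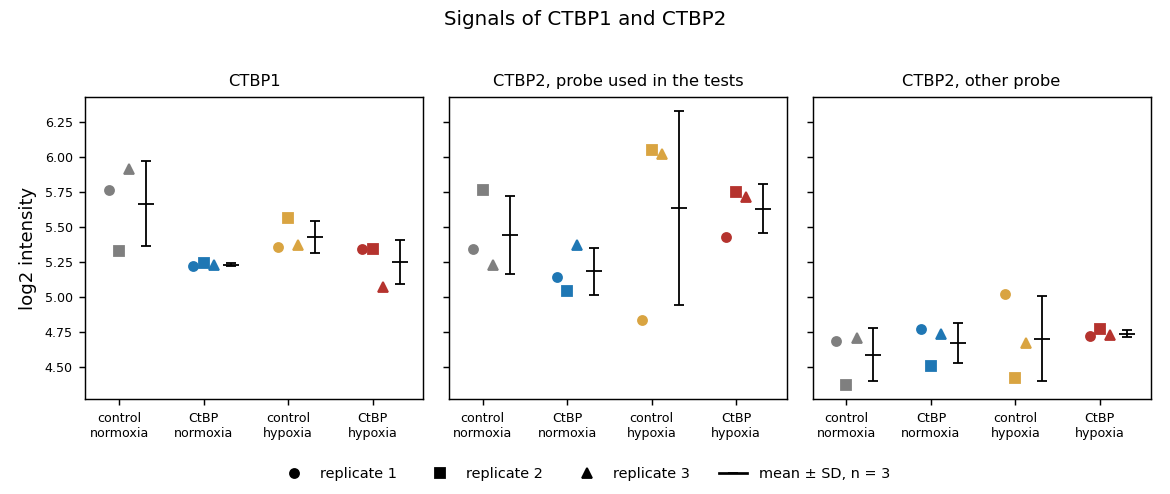
Log2 intensity of CTBP1 and of both CTBP2 probes on each of the 12 arrays, by group (points, single arrays; bars, group mean and SD). CTBP1 averaged 5.67 with control siRNA and 5.23 with CtBP siRNA in normoxia without overlap, as did the groups of 14.3% of all genes. The CTBP2 groups overlapped.

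The next question was how MCF7 cells with control siRNA responded to hypoxia. Classic targets of HIF rose steeply. PDK1, a kinase that inhibits pyruvate dehydrogenase, rose by 3.44 ± 0.19 on the log2 scale (limma adjusted p = 1.34e-07), and the stress gene NDRG1 rose by 3.33 ± 0.18 (adjusted p = 1.34e-07). VEGFA, the main growth factor for blood vessels, rose by 2.89 ± 0.16 (adjusted p = 1.34e-07). Outside the HIF lists, the cystine transporter SLC7A11, a member of the integrated stress response list, rose by 3.45 ± 0.37 (adjusted p = 6.36e-05). Among the falls were PLK1, a kinase of mitotic entry, with -2.35 ± 0.21 (adjusted p = 1.05e-05), the fatty acid elongase ELOVL2 with -2.65 ± 0.22 (adjusted p = 8.97e-06), and the histone gene H2BC14 with -3.24 ± 0.42 (adjusted p = 0.000241). In all, 718 genes rose and 1773 fell, of which 128 rose and 253 fell at least 2-fold. With each array centred on its median the split was 497 to 2377. The 3 arrays of a group all lay above the 3 of the other for 2437 of these 2491 genes, against 29.1% of all genes, where chance gives 10%. The genes were called on these same arrays, so the lack of overlap is no further evidence, here or in the comparisons below.

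The other large rises were the collagen prolyl hydroxylase P4HA1 (2.85), the glycolytic enzyme ALDOC (2.85), TMEM45A (2.79), the oxygen sensor EGLN3 (2.69), FAM162A (2.44), the clock repressor BHLHE40 (2.39), and PFKFB3 (2.33) and PFKFB4 (2.31), which make the activator of phosphofructokinase. The other large falls were the secreted protein gene MSMB (-2.45), the polyamine enzyme ODC1 (-2.42), the mitotic kinesin KIF20A (-2.28), CDK11B (-2.24, past the threshold in 15 of 20 alternatives and leave-outs), ART4 (-2.12), the histone genes H3C11 (-2.11) and H2BC8 (-2.09), MANSC1 (-1.99) and the Wnt antagonist DKK1 (-1.81). Of the measured HIF targets of glycolysis, 14 of 20 rose (16 adjusted over the list alone), with a median of 1.17. Camera gave an adjusted p of 3.96e-17, and the call was lost with an estimated correlation (adjusted p = 0.0766 with an estimated correlation). ENO1, a bright member, had a log2 fold change of 0.80 that did not pass (adjusted p = 0.177). Of the other HIF targets, 24 of 26 rose (24 adjusted over the list alone), the median was 2.13, and the call held (camera adjusted p = 1.15e-34, and adjusted p = 0.00018 with an estimated correlation). Its lone falling member was the carbonic anhydrase CA12 (-1.07, adjusted p = 0.0238), named after its value was seen.

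Camera called further lists as higher. Of 20 measured genes of the integrated stress response, which follows inhibited translation, 13 rose (13 adjusted over the list alone), with a median of 0.81 (camera adjusted p = 5.43e-14, and adjusted p = 0.0206 with an estimated correlation). Examples were DDIT3 (2.20), the lipoprotein receptor VLDLR (2.24) and the mTORC1 inhibitor DDIT4 (2.16). DDIT4 and STC2 were members of this list and of the other HIF targets, so the calls of both lists are not independent. Of 16 endoplasmic reticulum chaperones, 8 rose (10 adjusted over the list alone), among them HERPUD1 (1.64) and DNAJB9 (1.60). The list's median was 0.64 (camera adjusted p = 1.83e-08, but adjusted p = 0.219 with an estimated correlation), and 0.42 without the first control siRNA hypoxia array. Of 16 genes of cholesterol synthesis, 7 rose (9 adjusted over the list alone), such as STARD4, by about 2 on the log2 scale, and MSMO1 (0.86), with a median of 0.40 (camera adjusted p = 2.64e-05, but adjusted p = 0.209 with an estimated correlation). Of 25 p53 targets, 11 rose (13 adjusted over the list alone), including the stress cytokine GDF15 (1.43), TP53INP1 (1.23) and the DNA damage binding gene DDB2 (1.21). Their median was 0.36 (camera adjusted p = 1.12e-07, but adjusted p = 0.145 with an estimated correlation), and 0.56 with dim genes left out.

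Camera called 4 lists as lower. Of 29 mitosis genes, 24 fell (29 adjusted over the list alone), with a median of -1.18 and DLGAP5 (-1.66) and CENPF (-1.64) among the examples (camera adjusted p = 2.21e-23, but adjusted p = 0.0887 with an estimated correlation). Of 25 genes of oxidative phosphorylation, 11 fell (15 adjusted over the list alone), such as CYC1 (-1.06) and SDHC (-0.95), with a median of -0.36 (camera adjusted p = 3e-09, but adjusted p = 0.0916 with an estimated correlation). Of 20 estrogen receptor targets, 7 fell (8 adjusted over the list alone) and 1 rose. RERG (-1.49), the cochaperone FKBP4 (-1.12) and the progesterone receptor gene PGR (-1.01) fell, while the amino acid transporter SLC7A5 rose by 1.36. Their median was -0.36 (camera adjusted p = 0.00117, but adjusted p = 0.324 with an estimated correlation). It was -0.21 without the first control siRNA hypoxia array (adjusted p = 0.0486), and the call was lost with dim genes left out (adjusted p = 0.101). Of 29 DNA replication genes, 4 fell (6 adjusted over the list alone) and 1 rose, with POLE2 at -1.22 and MCM10 at -1.10. The median was -0.32 (camera adjusted p = 0.000225, but adjusted p = 0.451 with an estimated correlation), and without the first control siRNA hypoxia array the median was -0.18 and the call was lost (adjusted p = 0.0503). Leaving out the second or the third control siRNA normoxia array lowered the counts of genes to 470 up and 1148 down, or to 416 up and 1101 down.

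The remaining lists moved little in hypoxia with control siRNA. Mesenchymal genes had a median of 0.13 (camera adjusted p = 0.049, but adjusted p = 0.193 with an estimated correlation), and the call was lost without the first (adjusted p = 0.079) or the third (0.0528) control siRNA normoxia array, the first (0.113) or second (0.0901) control siRNA hypoxia array, or the third CtBP siRNA normoxia array (0.054). It was also lost after quantile normalization (0.108) and with dim genes left out (0.191), and the median was 0.05 after centring, 0.36 with dim genes left out and 0.07 without the first control siRNA hypoxia array. Epithelial genes had a median of -0.16 and did not pass (camera adjusted p = 0.175), although the keratin gene KRT18 fell by 1.23 and the desmosome gene DSP rose by 1.08. Without the second control siRNA hypoxia array this list passed (median -0.25, camera adjusted p = 0.0385). Notch targets had a median of 0.15 (camera adjusted p = 0.0606), with HEY1 up by 1.55 and HEY2, which fell by 1.24. They passed without the second (adjusted p = 0.0339) or the third (0.0464) control siRNA normoxia array or the first control siRNA hypoxia array (0.0486). The interferon response had a median of -0.04 (camera adjusted p = 0.25). It passed downwards without the third control siRNA normoxia array (median -0.12, 0.0464) or the first control siRNA hypoxia array (median -0.14, 0.0486). Not passing camera were also NF-kB inflammatory genes (median 0.10, adjusted p = 0.456), Wnt targets (0.09, adjusted p = 0.714), CtBP complex partners (0.04, adjusted p = 0.848) and pro-apoptotic BH3 and CtBP-linked death genes (0.12, adjusted p = 0.353). Within them SOD2 fell by 0.68, the deacetylase gene HDAC1 fell by 0.90 and the death gene HRK rose by 0.50. Markers of other cell types did not pass either, with medians of 0.13 for immune (adjusted p = 0.235), 0.10 for fibroblast (adjusted p = 0.203) and -0.08 for basal breast markers (adjusted p = 0.874). Reference genes had a median of -0.09 (adjusted p = 0.591), though PGK1, itself a glycolytic HIF target, rose by 1.86 and the actin gene ACTB fell by 1.05.

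**Figure D2:**
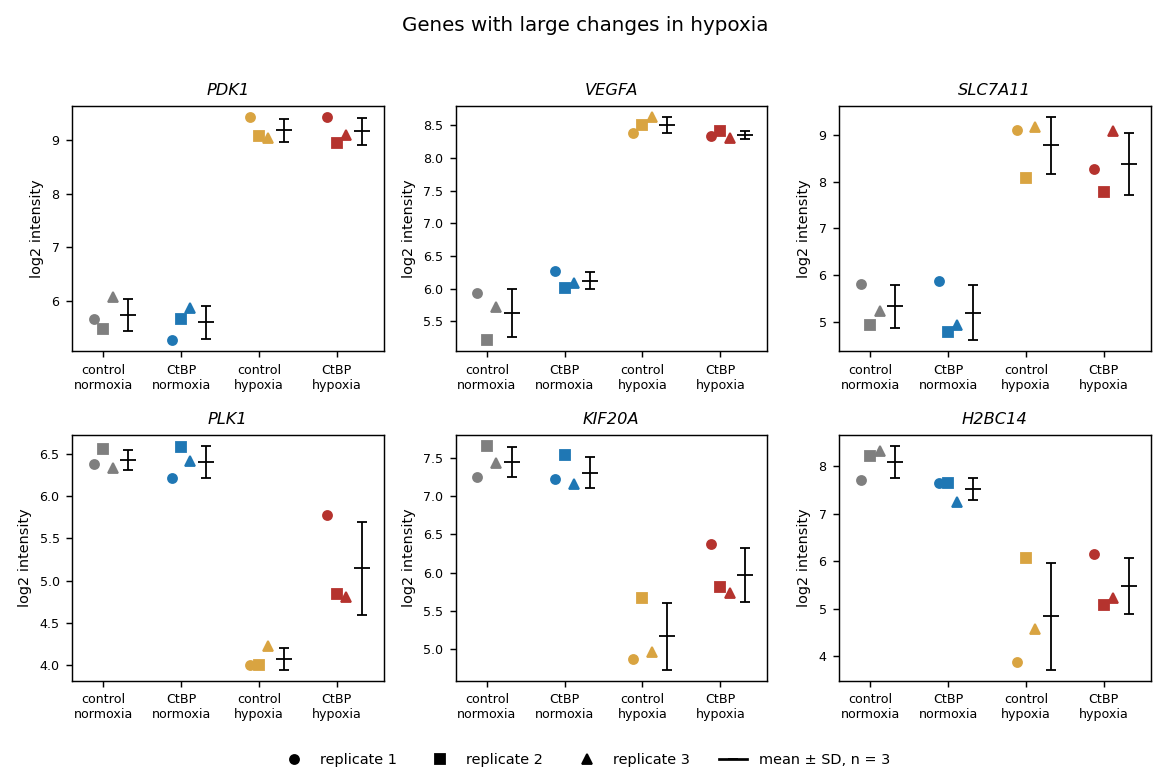
Log2 intensity of PDK1, VEGFA, SLC7A11, PLK1, KIF20A and H2BC14 on each of the 12 arrays, by siRNA and oxygen condition (points, single arrays; bars, group mean and SD, n = 3). PDK1 rose by 3.44 in hypoxia with control siRNA and by 3.56 with CtBP siRNA, and PLK1 fell by 2.35 and by 1.25.

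With CtBP siRNA, the classic HIF targets rose in hypoxia as well. PDK1 rose by 3.56 ± 0.19 (limma adjusted p = 1.56e-07), NDRG1 by 3.38 ± 0.18 (adjusted p = 1.56e-07) and BHLHE40 by 3.21 ± 0.25 (adjusted p = 5.75e-06). SLC7A11, of the integrated stress response list, rose by 3.18 ± 0.37 (adjusted p = 2e-04). H2BC14 fell by 2.04 ± 0.42 (adjusted p = 0.0104), ODC1 fell by 1.94 ± 0.41 (adjusted p = 0.0118), and IDH3A, an enzyme of the citric acid cycle, fell by 1.54 ± 0.20 (adjusted p = 0.000524). In all, 387 genes rose and 741 fell, 124 and 84 of them at least 2-fold. The groups did not overlap for 1121 of these 1128 genes, against 26.2% of all genes and 10% by chance. Further large rises were TMEM45A (2.98), EGLN3 (2.86), ALDOC (2.77), PFKFB3 (2.77), VLDLR (2.65), ANKRD37 (2.52), the neuronal enolase ENO2 (2.48) and the mitophagy receptor BNIP3L (2.45). Further large falls were OR7E13P (-2.02), ART4 (-1.86), H3C11 (-1.83), ELOVL2 (-1.81), the spliceosomal RNA gene RNU4-2 (-1.59), the interleukin receptor IL1R1 (-1.58), ATF7IP (-1.49), TENT5C (-1.48) and NR5A2 (-1.45).

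Of the glycolytic HIF targets 16 of 20 rose (19 adjusted over the list alone), with a median of 1.38 (camera adjusted p = 1.07e-28, and adjusted p = 0.0177 with an estimated correlation). Of the other HIF targets 22 of 26 rose (24 adjusted over the list alone), with a median of 2.03 (camera adjusted p = 4.97e-50, and adjusted p = 4.41e-05 with an estimated correlation). Of the integrated stress response 10 of 20 rose (14 adjusted over the list alone), with a median of 0.69 (camera adjusted p = 1.95e-15, and adjusted p = 0.015 with an estimated correlation). Of 29 mitosis genes 13 fell (22 adjusted over the list alone), with a median of -0.71, and KIF20A (-1.33), PLK1 (-1.25), AURKA (-1.24) and TOP2A (-1.22) fell most (camera adjusted p = 3.78e-19, but adjusted p = 0.143 with an estimated correlation). Endoplasmic reticulum chaperones had 4 of 16 up (8 adjusted over the list alone) and a median of 0.43 (camera adjusted p = 2.43e-06, but adjusted p = 0.412 with an estimated correlation). P53 targets had 2 of 25 up (5 adjusted over the list alone), GDF15 (1.57) and DDB2 (0.97), and a median of 0.23 (camera adjusted p = 0.000406, but adjusted p = 0.412 with an estimated correlation), which was 0.14 without the third CtBP siRNA normoxia array and 0.15 without the second CtBP siRNA hypoxia array. DNA replication genes had a median of -0.13 and did not pass (camera adjusted p = 0.0767). They passed without the first (adjusted p = 0.0198) or second (0.0333) control siRNA hypoxia array, the first CtBP siRNA normoxia array (0.0307) or the second CtBP siRNA hypoxia array (0.00801).

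Smaller shifts with CtBP siRNA lost their calls without single arrays. Cholesterol synthesis had a median of 0.10 (camera adjusted p = 0.0169, but adjusted p = 0.47 with an estimated correlation), and lost its call without the second (median 0.05, adjusted p = 0.111) or the third (0.02, adjusted p = 0.117) CtBP siRNA hypoxia array, while its median was 0.26 without the first. Oxidative phosphorylation had a median of -0.16 (camera adjusted p = 0.03, but adjusted p = 0.47 with an estimated correlation), and lost its call without the second CtBP siRNA normoxia array (median -0.13, 0.0752) or the first (-0.15, adjusted p = 0.0547) or second (-0.19, adjusted p = 0.0676) CtBP siRNA hypoxia array, so its median moved little. Estrogen receptor targets had a median of -0.13 (camera adjusted p = 0.0244, but adjusted p = 0.47 with an estimated correlation), and lost their call without the first (0.0509) or the third (0.0644) CtBP siRNA normoxia array or the first CtBP siRNA hypoxia array (0.0547). Their median was -0.26 without the second CtBP siRNA normoxia array, -0.06 without the third and -0.26 with dim genes left out. Quantile normalization ended the calls of estrogen receptor targets (0.0549) and oxidative phosphorylation (0.0735), and so did leaving dim genes out (0.251 and 0.288). The gene counts fell to 200 up and 256 down without the second CtBP siRNA normoxia array, to 237 and 419 without the third, and the falls to 473 without the first. Without the third CtBP siRNA hypoxia array 328 genes fell.

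Set side by side, hypoxia changed many genes in the same direction with either siRNA. Of the genes called, 263 rose in both comparisons, against 15.1 if calls were independent, and 607 fell in both, against 71.4. No gene was called in opposite directions (0 in each). PDK1, NDRG1, SLC7A11, TMEM45A and ALDOC led the shared rises, and H2BC14, ODC1, ART4, H3C11 and ELOVL2 the shared falls. Across all genes, which are not independent replicates, the log2 fold changes correlated with r = 0.77. Among genes called with control siRNA the change with CtBP siRNA had a median of 0.63 of that with control siRNA, and 96.6% had the same sign. Among genes called with CtBP siRNA the change with control siRNA had a median of 1 times that with CtBP siRNA. Both ratios depend on which comparison picked the genes, since a change picked for its size tends to be smaller in the other comparison. The 0.63 therefore does not by itself show a weaker response with CtBP siRNA, and no single gene passed in the interaction. The ratios were not computed without the first control siRNA hypoxia array. Without the second CtBP siRNA normoxia array 156 rose and 233 fell in both, and the shared falls were 400 without the first, 357 without the third and 289 without the third CtBP siRNA hypoxia array. Averaged over both siRNAs, hypoxia raised 1207 genes and lowered 2495 (826 and 3128 with arrays centred on their medians), 126 and 149 of them at least 2-fold.

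The knockdown was then examined in normoxia, where 4 genes passed. ACTA2, the smooth muscle actin, rose by 1.53 ± 0.17 (limma adjusted p = 0.00422, n = 3 arrays per group). It was dim, with 3.62 with control siRNA and a mean of 4.33 over all arrays, where the median of genes was 4.45, so the size of its change is given only as measured. HEG1, CNNM1, EDA2R, ZNF404, CDK11B, RNU4-2, ORM2 and ELOVL2-AS1, named elsewhere, also lay below that median. TIGAR, a p53 target that restrains glycolysis, rose by 1.17 ± 0.15 (adjusted p = 0.0102). SLC4A10, a bicarbonate transporter, fell by 1.45 ± 0.16 (adjusted p = 0.00403), and the kinase CDK5 fell by 0.84 ± 0.12 (adjusted p = 0.031). These 4 genes were the calls of the fit, against 1104 of 18404 at an unadjusted p under 0.05, where chance alone gives a share of 0.05. With the replicate block 40 genes rose and 12 fell. The groups did not overlap for 4 of the 4, against 14.3% of all genes and 10% by chance. With every probe taken as a feature none of the 4 passed, with adjusted p of 0.0535 for ACTA2, 0.0863 for TIGAR, 0.0506 for SLC4A10 and 0.143 for CDK5.

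Genes of the p53 pathway were higher as a group. Of 25 measured p53 targets 24 had positive log2 fold changes with a median of 0.50, 1 passed over all genes (7 with the replicate block) and 17 passed adjusted over the list alone. The p53 call held with either correlation (camera adjusted p = 6.96e-27, and adjusted p = 0.0257 with an estimated correlation). The cell death gene BAX had 0.50 (adjusted p = 0.639). Mitosis genes lay lower, with a median of -0.22 and 2 of 29 positive, and DNA replication genes had a median of -0.19 and 3 of 29 positive. In limma 0 genes of either list passed over all genes. At an unadjusted p under 0.05, which a share of 0.05 passes by chance, 2 mitosis and 3 DNA replication genes were lower. Camera called both lists (adjusted p = 4.32e-05), and neither held with an estimated correlation (adjusted p = 0.701 with an estimated correlation). Without the third control siRNA normoxia array the mitosis median was -0.13. Other HIF targets had a median of 0.09 (camera adjusted p = 0.0291, but adjusted p = 0.45 with an estimated correlation), which was lost without the first (adjusted p = 0.0719) or second (0.257) control siRNA normoxia array or the first (0.123) or the third (0.0927) CtBP siRNA normoxia array, after quantile normalization (0.0722) and with dim genes left out (0.115). Their median was 0.02 without the second control siRNA normoxia array, 0.14 without the third and 0.15 with dim genes left out. Epithelial genes had a median of 0.08 (camera adjusted p = 0.0157, but adjusted p = 0.666 with an estimated correlation), which was lost without the first control (0.0926) or the third CtBP siRNA normoxia array (0.0553) and with dim genes left out (0.117). Interferon response genes had a median of -0.08 (camera adjusted p = 0.0515) and Notch targets one of 0.08 (0.0515), and both passed with the replicate block (adjusted p = 0.0185 and 0.03). Without the block neither list passed with an estimated correlation. Interferon response genes also passed without the third control siRNA normoxia array (median -0.16, 0.00189) or the first CtBP siRNA normoxia array (median -0.15, 0.00213), and Notch targets without the third control siRNA normoxia array (0.0383).

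Normoxia calls were lost without single arrays, although the log2 fold changes moved little. TIGAR no longer passed without the first (adjusted p = 0.107), second (0.0565) or the third (0.0774) CtBP siRNA normoxia array, where its log2 fold change was 1.14, 1.19 and 1.19, against 1.17. CDK5 no longer passed without any of these (0.233, 0.162 and 0.0798) or without the second (0.146) or the third (0.19) control siRNA normoxia array, with log2 fold changes between -0.77 and -0.89, against -0.84. Leaving out the first control siRNA hypoxia array gave 18 genes up and 10 down, and leaving out the third CtBP siRNA hypoxia array gave 10 and 7. The counts were 6 and 2 without the first control siRNA normoxia array, 3 and 1 without the second and 2 and 1 without the third. They were 4 and 3 without the second control siRNA hypoxia array, 4 and 3 without the first CtBP siRNA hypoxia array and 4 and 2 without its second. They were 1 and 1 without the first, 2 and 1 without the second, and 1 and 1 without the third CtBP siRNA normoxia array.

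In hypoxia most of the genes that the knockdown called were higher with CtBP siRNA. The actin-bundling gene LCP1 rose by 1.56 ± 0.21 (limma adjusted p = 0.0149), the annexin ANXA3 by 1.54 ± 0.23 (adjusted p = 0.0175) and the breast secretory gene MUCL1 by 1.28 ± 0.13 (adjusted p = 0.00292). SLC2A1, the glucose transporter GLUT-1 and a HIF target, rose by 1.07 ± 0.15 (adjusted p = 0.0149), and CROT, which handles fatty acids in peroxisomes, rose by 1.13 ± 0.16 (adjusted p = 0.0149). MED10, a subunit of the Mediator complex, fell by 0.92 ± 0.13 (adjusted p = 0.0173), and HMGCS1, an enzyme of cholesterol synthesis, fell by 0.64 ± 0.10 (adjusted p = 0.0185). In all, 56 genes rose and 8 fell, against 203 and 41 with the replicate block and 2319 genes at an unadjusted p under 0.05. The groups did not overlap for 64 of the 64, against 15.4% of all genes and 10% by chance. The other large rises were HEG1 (1.26), PLK1 (1.07), the cytoskeletal gene CSRP1 (1.03), the histone gene H2BC12 (1.03), KRT18 (0.99), CNNM1 (0.99) and EDA2R (0.98), a p53-regulated receptor. The other falls included the zinc finger gene ZNF404 (-1.01), SLC4A10 (-0.95), DNAJC21 (-0.77), ZGRF1 (-0.77) and the Fanconi anemia gene FANCB (-0.77).

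P53 targets were again higher, with a median of 0.29, 1 of 25 passing over all genes (5 with the replicate block), TP53I3 (0.94 ± 0.18, adjusted p = 0.0488), and 10 adjusted over the list alone. Camera gave an adjusted p of 3.7e-08 (adjusted p = 0.219 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.32 with 0 rising over all genes (limma), 14 higher at an unadjusted p under 0.05 and 12 of 25 adjusted over the list alone (camera adjusted p = 1.37e-08, but adjusted p = 0.219 with an estimated correlation). Without the first control siRNA hypoxia array this median was 0.21. Epithelial genes had a median of 0.28, with KRT18 passing and 5 of 22 adjusted over the list alone (camera adjusted p = 5.51e-06, but adjusted p = 0.219 with an estimated correlation). Without that array their median was 0.15. Cholesterol synthesis had a median of -0.23, with 1 of 16 falling and 5 adjusted over the list alone (camera adjusted p = 4.41e-05, but adjusted p = 0.419 with an estimated correlation), and a median of -0.41 without that array, -0.11 without the third control siRNA hypoxia array and -0.09 without the first CtBP siRNA hypoxia array.

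Other list calls in hypoxia changed without that array. Without it glycolytic HIF targets went from a median of 0.31 (camera adjusted p = 0.0102, but adjusted p = 0.692 with an estimated correlation) to -0.02 (adjusted p = 0.891), and they also lost the call without the second CtBP siRNA hypoxia array (0.0711) and with dim genes left out (0.285). Endoplasmic reticulum chaperones went from -0.21 (camera adjusted p = 0.000489, but adjusted p = 0.692 with an estimated correlation) to 0.02 (adjusted p = 0.807), and their median was -0.38 without the second and -0.32 without the third control siRNA hypoxia array. Mitosis genes, with a median of 0.11 (camera adjusted p = 0.0158, but adjusted p = 0.725 with an estimated correlation), lost the call without it (0.157) and without the first CtBP siRNA hypoxia array (median -0.10, adjusted p = 0.727), after quantile normalization (median 0.06, adjusted p = 0.182) and with dim genes left out (0.285). Their median was 0.19 without the second control siRNA hypoxia array, 0.20 without the second CtBP siRNA hypoxia array and 0.25 without the third. DNA replication genes went from -0.01 (adjusted p = 0.757) to -0.18 (adjusted p = 2.91e-05). Other HIF targets lay at the threshold (median 0.19, camera adjusted p = 0.05 when rounded, just past the threshold, but adjusted p = 0.419 with an estimated correlation), and lost the call without the second (0.0529) or the third (0.0539) control siRNA normoxia array, the first (0.0836), second (0.0867) or the third (0.0782) control siRNA hypoxia array, or the first (0.0788) or second (median 0.10, 0.155) CtBP siRNA hypoxia array, and after quantile normalization (0.202), centring (0.0548) or leaving dim genes out (0.543).

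The gene counts of this comparison moved with every array left out. MUCL1 passed in 21 of 21 alternatives and leave-outs, LCP1 and CROT in 18, SLC2A1 and MED10 in 17 and ANXA3 in 15, while KRT18 passed in 8, TP53I3 in 7 and PLK1 in 6. Without the first, second or the third control siRNA hypoxia array 9, 239 and 6 genes rose and 1, 37 and 1 fell. Without the first, second or the third CtBP siRNA hypoxia array 6, 18 and 9 rose and 0, 6 and 1 fell. Without the first, second or the third control siRNA normoxia array 34, 17 and 19 rose and 6, 3 and 5 fell, and without the CtBP siRNA normoxia arrays 25, 19 and 25 rose and 5, 4 and 6 fell. With the replicate block but without the first control siRNA hypoxia array 33 rose and 4 fell.

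Which oxygen condition had more calls depended on the fit. The full fit called 56 up and 8 down in hypoxia against 2 and 2 in normoxia, but the order turned with a contrast's own 6 arrays (1 and 0 in hypoxia, 8 and 9 in normoxia). It also turned without the first control siRNA hypoxia array (9 and 1, against 18 and 10), the first CtBP siRNA hypoxia array (6 and 0, against 4 and 3) or the third (9 and 1, against 10 and 7), and with the block without the first control siRNA hypoxia array (33 and 4, against 65 and 26).

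**Figure D3:**
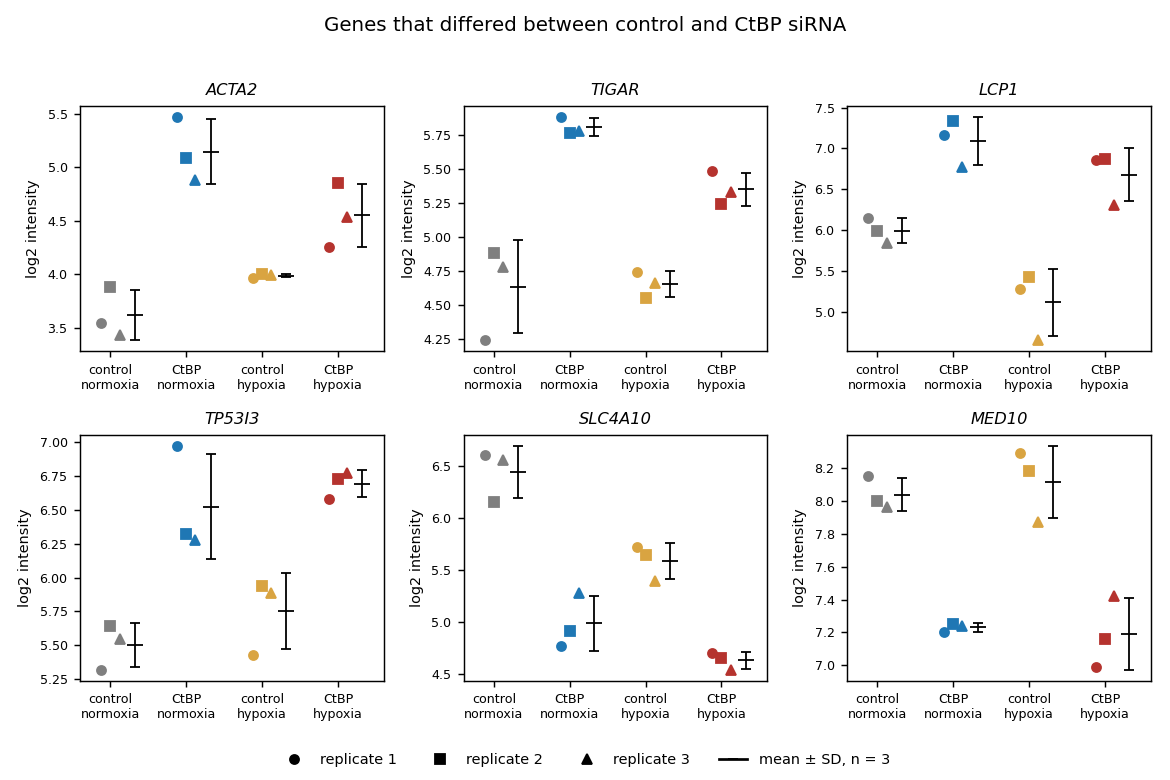
Log2 intensity of ACTA2, TIGAR, LCP1, TP53I3, SLC4A10 and MED10 on each of the 12 arrays, by siRNA and oxygen condition (points, single arrays; bars, group mean and SD, n = 3). Averaged over oxygen conditions LCP1 rose by 1.33 with CtBP siRNA and SLC4A10 fell by 1.20.

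Averaged over normoxia and hypoxia, the knockdown effect had a median standard error of 0.098, against 0.139 in either condition alone. TGFB2, a ligand of the TGF-beta pathway, rose by 2.31 ± 0.34 (limma adjusted p = 0.00536), ANXA3 by 1.45 ± 0.16 (adjusted p = 0.000941), LCP1 by 1.33 ± 0.15 (adjusted p = 0.000941) and MUCL1 by 1.01 ± 0.09 (adjusted p = 0.000364). The vasoconstrictor gene EDN1 rose by 1.04 ± 0.14 (adjusted p = 0.00287). SLC4A10 fell by 1.20 ± 0.11 (adjusted p = 0.000364), MED10 fell by 0.86 ± 0.10 (adjusted p = 0.000941), and the clathrin heavy chain gene CLTC fell by 0.60 ± 0.10 (adjusted p = 0.0102). In all, 140 genes rose and 32 fell, against 287 and 77 with the replicate block, and 10 rose and 1 fell at least 2-fold. The other large rises were SPINK1 (1.34), which passed in 9 of 20 alternatives and leave-outs, CROT (1.06), ACTA2 (1.05), the caveolar gene CAV1 (1.02) and, each by about 1, PDLIM1, HEG1 and DOCK11. The other falls were DNAJC21 (-0.78), the disulfide isomerase P4HB (-0.77), ORM2 (-0.76), CEP128 (-0.67), RAB31 (-0.67), UGCG (-0.66), CIT (-0.57) and CDK5 (-0.55).

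Of 25 p53 targets 25 had positive changes with a median of 0.46, and 8 rose (14 with the replicate block, 18 adjusted over the list alone). TP53I3 rose by 0.98 ± 0.13 (adjusted p = 0.00287), TIGAR by 0.93 ± 0.11 (adjusted p = 0.000941), SESN1, a stress sensor that curbs mTORC1, by 0.82 ± 0.12 (adjusted p = 0.00538) and SPATA18 by 0.71 ± 0.14 (adjusted p = 0.0281). MDM2, the ubiquitin ligase of p53 and itself a target, had 0.11 (adjusted p = 0.714). Camera gave an adjusted p of 2.15e-20 (adjusted p = 0.0596 with an estimated correlation). Epithelial genes had a median of 0.21, with 0 of 22 rising over all genes (limma), 10 higher at an unadjusted p under 0.05 and 7 adjusted over the list alone (camera adjusted p = 5.14e-06, but adjusted p = 0.209 with an estimated correlation), and a median of 0.13 without the first control siRNA hypoxia array. Oxidative phosphorylation genes had a median of 0.16 (camera adjusted p = 6.08e-05, but adjusted p = 0.395 with an estimated correlation). Cholesterol synthesis had a median of -0.15, with INSIG1 (-0.52) and HMGCS1 (-0.42) falling (camera adjusted p = 0.000645, but adjusted p = 0.421 with an estimated correlation), and a median of -0.23 without that array. Other HIF targets had a median of 0.13 with 0 of 26 rising over all genes (limma), 5 higher at an unadjusted p under 0.05 and 2 adjusted over the list alone (camera adjusted p = 0.00585, but adjusted p = 0.26 with an estimated correlation), and with dim genes left out the median was 0.21 and the call was lost (adjusted p = 0.174).

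The weaker averaged lists lost calls without single arrays. Endoplasmic reticulum chaperones had a median of -0.14 (camera adjusted p = 0.00391, but adjusted p = 0.563 with an estimated correlation), lost without the first control siRNA hypoxia array (median -0.03, adjusted p = 0.401), and a median of -0.09 without the third CtBP siRNA normoxia array. Glycolytic HIF targets had a median of 0.17 with SLC2A1 rising by 0.81 ± 0.10 (camera adjusted p = 0.02, but adjusted p = 0.563 with an estimated correlation). Their call was lost without the first control siRNA normoxia array (0.0713), the first control siRNA hypoxia array (median 0.02, 0.401), the third CtBP siRNA normoxia array (0.0829), or the second (0.0691) or the third (0.0516) CtBP siRNA hypoxia array, after quantile normalization (0.0587) and with dim genes left out (0.282). DNA replication genes had a median of -0.10, with RRM1 (-0.51) and CDC6 (-0.45) falling (camera adjusted p = 0.02, but adjusted p = 0.7 with an estimated correlation). Without the first control siRNA hypoxia array their median was -0.21 (adjusted p = 2.74e-08), and without the second CtBP siRNA normoxia array it was -0.06 (0.0113). Their call was lost without the third control siRNA normoxia array (median -0.05, 0.112), the second (median 0.04, 0.612) or the third (0.0731) control siRNA hypoxia array, the first CtBP siRNA normoxia array (0.0554), or the first (median -0.06, 0.0878) or the third (0.0727) CtBP siRNA hypoxia array. Interferon response genes had a median of -0.04 (camera adjusted p = 0.0421, but adjusted p = 0.563 with an estimated correlation), and 7 arrays ended that call. These were the first (0.0872) and second (0.174) control siRNA normoxia, the first control siRNA hypoxia (0.335), the second (0.0801) and the third (0.157) CtBP siRNA normoxia and the second (0.0765) and the third (0.0835) CtBP siRNA hypoxia arrays. Quantile normalization (0.128) and leaving dim genes out (median -0.02, 0.226) ended it too. The median was -0.02 and 0.00 without the second control siRNA normoxia and the first control siRNA hypoxia array and -0.01 without the third CtBP siRNA normoxia array. It was -0.09 without the third control siRNA normoxia or the first CtBP siRNA hypoxia array, and -0.08 without the third control siRNA hypoxia or the first CtBP siRNA normoxia array.

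Gene counts of the averaged knockdown also moved with single arrays. Without the second or the third control siRNA normoxia array 81 and 78 genes rose and 17 and 18 fell, and without the first 21 fell. Without the second control siRNA hypoxia array 240 rose, and without the third 21 fell. Without the first or second CtBP siRNA normoxia array 72 and 61 rose and 14 fell each time, and without the first CtBP siRNA hypoxia array 88 rose.

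The design next asks whether the knockdown acts differently in hypoxia and normoxia. Mitosis and oxidative phosphorylation genes had higher knockdown effects in hypoxia, with a median difference of 0.36 for mitosis and 0.25 for oxidative phosphorylation (camera adjusted p = 3.43e-08 for both). Neither call held with an estimated correlation (adjusted p = 0.596 for mitosis and adjusted p = 0.546 for oxidative phosphorylation with an estimated correlation). These 2 of 8 called lists kept their calls at the preset correlation in each of 12 leave-outs, although the mitosis median was 0.14 without the first CtBP siRNA hypoxia array. P53 targets had a median difference of -0.16 (camera adjusted p = 0.00211), cholesterol synthesis one of -0.16 (adjusted p = 0.00652), and the integrated stress response one of -0.22 (adjusted p = 0.0157). None of these 3 held (adjusted p = 0.596 each with an estimated correlation). DNA replication (0.18, adjusted p = 0.0157), epithelial genes (0.14, adjusted p = 0.0291) and endoplasmic reticulum chaperones (-0.17, adjusted p = 0.0157) were the remaining calls. They did not hold either (adjusted p = 0.756 for DNA replication and chaperones and adjusted p = 0.596 for epithelial genes with an estimated correlation). Other HIF targets had a median difference of 0.04 (camera adjusted p = 0.874).

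No single gene passed in the interaction. The limma fit called 0 genes, and 0 with the replicate block. Of 18404 genes, 935 had an unadjusted p under 0.05, close to the share of 0.05 that chance alone gives. The smallest adjusted p was 0.445, for ELOVL2-AS1 (1.67). Next by p came DUX4 (1.25, adjusted p = 0.96) and ZNF404 (-1.24, adjusted p = 0.96), which did not pass either. Across all genes, which are not independent replicates, the 2 knockdown effects correlated with r = 0.341, and 59 of the 64 genes called in hypoxia had the same sign in normoxia. The calls shared 1 fall, SLC4A10, and 0 rises, against 4 and 30 with the replicate block. SLC4A10 was not shared without the first or the third control siRNA hypoxia array or the first or the second CtBP siRNA hypoxia array (0 falls each). Shared rises numbered 3 without the first control siRNA normoxia or the first control siRNA hypoxia array, 2 without the second control siRNA hypoxia array, and 1 without the second CtBP siRNA normoxia or the third CtBP siRNA hypoxia array.

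Calls of the other list differences in the interaction were lost without single arrays. Without the first control siRNA hypoxia array DNA replication (median -0.02, adjusted p = 0.925), epithelial genes (-0.01, adjusted p = 0.57) and chaperones (0.06, adjusted p = 0.925) no longer passed. Without it the median was -0.11 for the integrated stress response (adjusted p = 0.0285) and -0.25 for cholesterol synthesis (0.00016), which still passed. DNA replication was also lost without the third control siRNA normoxia (0.172), the first CtBP siRNA normoxia (0.0857) or the second CtBP siRNA hypoxia array (0.376), and with dim genes left out (0.139), and chaperones without either of the last 2 arrays (0.0734 and 0.0825). Without the second control siRNA hypoxia array the median was 0.37 for DNA replication, 0.22 for epithelial genes and -0.29 for chaperones, and for chaperones it was -0.27 without the third. Epithelial genes were lost without the second (0.0557) or the third (0.0855) control siRNA normoxia, the first (0.0734) or second (0.0597) CtBP siRNA normoxia or the second CtBP siRNA hypoxia array (0.102), after quantile normalization (0.0855) and with dim genes left out (0.167). Their median was 0.08 without the third control siRNA hypoxia or the first CtBP siRNA hypoxia array. P53 targets lost their call without the first CtBP siRNA normoxia (median -0.11, 0.109) or the third CtBP siRNA hypoxia array (median -0.19, 0.0543), and cholesterol synthesis without the third control siRNA hypoxia (0.119) or first CtBP siRNA hypoxia array (median -0.10, 0.178). The cholesterol synthesis median was -0.26 without the third CtBP siRNA hypoxia array. The integrated stress response was lost without the third control siRNA normoxia (0.0975), the third control siRNA hypoxia (median -0.10, 0.0971) or the first CtBP siRNA normoxia array (median -0.06, 0.257), and its median was -0.14 without the second CtBP siRNA hypoxia array. Glycolytic HIF targets (0.23, adjusted p = 0.0802) passed without the first control siRNA normoxia (0.0233), the second (0.00392) or the third (0.00805) control siRNA hypoxia, the third CtBP siRNA normoxia (0.0325) or the first CtBP siRNA hypoxia array (0.0226). Without the first control siRNA hypoxia array their median changed sign to -0.05 (camera adjusted p = 0.871). Estrogen receptor targets (median 0.13, adjusted p = 0.0802) passed with the replicate block (0.0386) and without the second control siRNA normoxia (0.0128), the second (0.0235) or the third (median 0.23, 0.00618) control siRNA hypoxia, the third CtBP siRNA normoxia (0.0325) or the first CtBP siRNA hypoxia array (0.046). Without the first control siRNA hypoxia array their median changed sign to -0.06 (camera adjusted p = 0.925). Reference genes, with a median of 0.12, also passed without the second control siRNA hypoxia array (median 0.25, camera adjusted p = 0.00947).

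**Figure D4:**
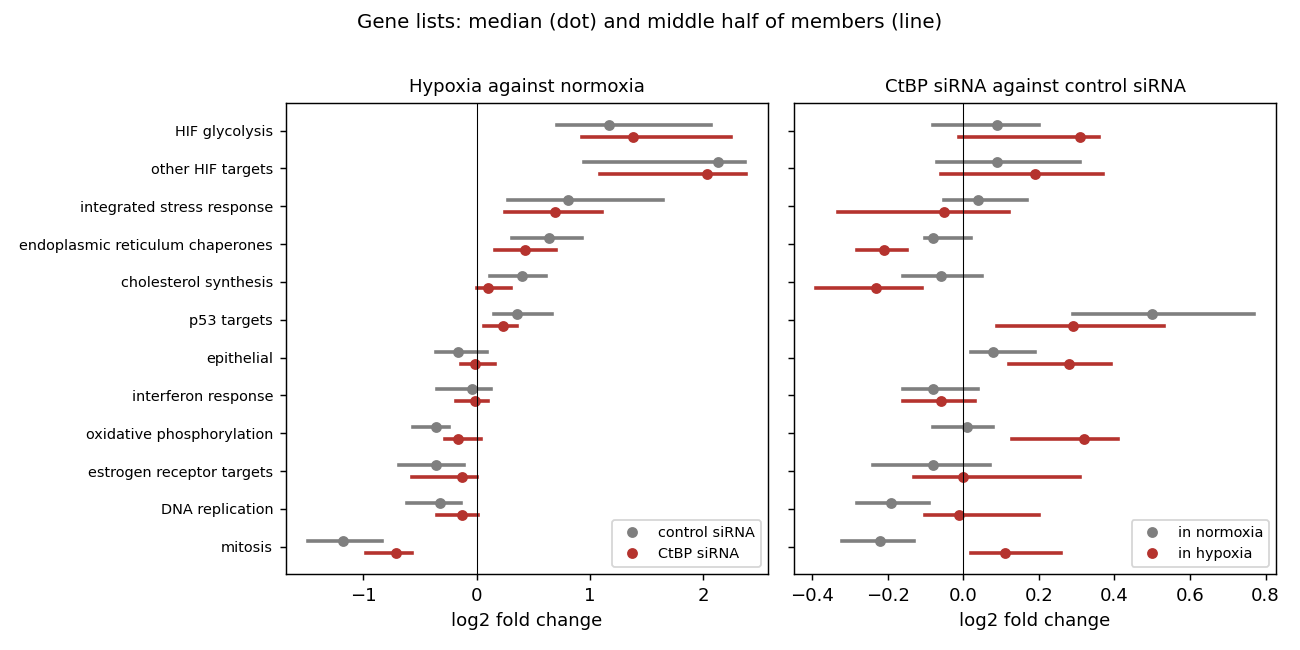
Log2 fold changes of the measured members of 12 gene lists (dots, median; lines, from the lower to the upper quartile of the members) for hypoxia against normoxia with either siRNA, and for CtBP against control siRNA in either oxygen condition. HIF targets outside glycolysis had medians of 2.13 and 2.03 in hypoxia, and p53 targets had medians of 0.50 and 0.29 with CtBP siRNA.

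Finally, the averaged knockdown and the averaged hypoxia responses were compared. SLC2A1, TMEM45B, RND3, DDB2 and SPATA18 led 27 genes that rose with both (9.2 if calls were independent between the comparisons). SLC2A1 rose by 0.81 ± 0.10 with CtBP siRNA and by 1.32 ± 0.10 in hypoxia, and DDB2 by 0.65 ± 0.11 and 1.09 ± 0.11. A group of 45 genes rose with CtBP siRNA and fell in hypoxia (19 if independent), led by H2BC12, MUCL1, LCP1, EMP2 and S100A16. With both, 7 genes fell (4.3 if independent), led by RAB31, SLC4A10, CIT, CDK5 and RPA2. Another 7 fell with CtBP siRNA and rose in hypoxia (2.1 if independent), led by P4HB, INSIG1, ZGRF1, CDC6 and MIR301A. The calls were not independent, because both averages came from the same arrays and the same residual variance per gene. This can raise shared calls in any direction. Every pair of directions, the opposite ones included, lay above its independent value, so the excess cannot be read as a shared response. The correlation across genes was r = -0.091. With the replicate block 50 genes rose with both, 25 fell with both and 118 rose with CtBP siRNA and fell in hypoxia, and 11 fell with CtBP siRNA and rose in hypoxia. Shared rises numbered 15 and 14 without the second and the third control siRNA normoxia array, 16 without the third control siRNA hypoxia array, and 13 and 10 without the first and second CtBP siRNA normoxia array. Shared falls numbered 4 without the second control siRNA normoxia array, 17 without the first control siRNA hypoxia array and 3 without the first or the second CtBP siRNA normoxia array. The 45 became 25, 21 and 25 without the 3 control siRNA normoxia arrays in turn, 116 without the second control siRNA hypoxia array, 23 and 20 without the first and second CtBP siRNA normoxia array and 23 without the first CtBP siRNA hypoxia array. Genes that fell with CtBP siRNA and rose in hypoxia numbered 13 without the second control siRNA hypoxia array.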

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

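The tests of the interaction lists and of the p53 targets below were chosen after the results were seen, while the tests of the small CTBP1 and CTBP2 change and the splits of the arrays were chosen before.

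The knockdown effects of 8 lists differed between hypoxia and normoxia by camera, with median differences of 0.36 for mitosis, 0.25 for oxidative phosphorylation, 0.18 for DNA replication, 0.14 for epithelial genes, -0.16 for p53 targets, -0.16 for cholesterol synthesis, -0.17 for endoplasmic reticulum chaperones and -0.22 for the integrated stress response. Members of a list that vary together between arrays may account for all 8 calls, since with an estimated correlation the smallest adjusted p among them was 0.546. The first control siRNA hypoxia array alone is argued against for mitosis, oxidative phosphorylation (adjusted p = 7.88e-06 each without it), p53 targets (0.00296) and cholesterol synthesis (0.00016), although other single arrays ended the last 2 calls. It cannot be told apart from other arrays for DNA replication (0.925), epithelial genes (0.57) and chaperones (0.925), which lost their calls without it but also without other single arrays, nor for the integrated stress response (0.0285), whose median went from -0.22 to -0.11. A biological difference between the knockdown effects in hypoxia and in normoxia stays open.

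The p53 targets were higher with CtBP siRNA by a median of 0.46 in the averaged comparison. An innate immune response to the siRNA is argued against, since the upper quartile of the interferon response members was 0.01, and so is a single array, since the highest camera adjusted p over 12 leave-outs was 4.67e-17, although with an estimated correlation the averaged call itself was lost (adjusted p = 0.0596). Off-target activity of the siRNA stays open, because the arrays carry 1 CtBP siRNA label, which does not say whether it stands for a single sequence or a pool. A p53 response to lower CtBP stays open beside it as a hypothesis.

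With CtBP siRNA, CTBP1 changed by -0.31 and CTBP2 by -0.13 on the log2 scale on average (CTBP2 by -0.33 without the first control siRNA hypoxia array), and neither passed over all genes, although CTBP1 did over the 3 probes of both genes alone in limma (adjusted p = 0.0266). SiRNA labels without any effect on the arrays are argued against. Of 32 swaps of siRNA labels within replicate pairs only 1, the real labelling, called as many genes as the 364 of the blocked averaged comparison. The highest of the others called 1, although swaps mix arrays of both siRNAs, which lowers their counts. A limit that holds all signals at this brightness to changes under 1 is argued against. Of genes within 5 percentiles of the CTBP1 probe, 2.34% (43 of 1840) changed by at least 1 with averaged hypoxia. Over all 18404 genes 126 rose and 149 fell by that much. A partial compression was not tested by this, because large changes could be reduced and still exceed 1. Compression of the single CTBP1 and CTBP2 probes, and a protein loss larger than that of the transcript, stay open and were not tested.

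Probes without a single gene name were outside the gene tests, and 22 of 13163 passed in the averaged knockdown and 1401 in averaged hypoxia, of which 928 were higher and 473 lower.

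Other splits of the arrays were run for every count of genes. For each single contrast 10 splits of its 6 arrays are too few for a share under 0.05, and 1 of 10, the real split, gave as many genes each time. The real counts and the highest of the other splits were 4 and 0 for the knockdown in normoxia, 64 and 2 for the knockdown in hypoxia, 2491 and 0 for hypoxia with control siRNA and 1128 and 0 for hypoxia with CtBP siRNA. Among the 4 splits of each knockdown contrast that part all replicate pairs, the highest other count was 0. For the averaged knockdown 1 of 100 drawn splits gave as many genes (172, against 1 in the highest other), as did 1 of 32 swaps with the replicate block. This argues against chance there but cannot exclude it, since 1 is the smallest count these splits can give. Other splits also mix arrays of both groups, which lowers their counts. The same holds for averaged hypoxia, with 1 of 100 (3702, against 437). For the interaction the real count was 0, so 100 of 100 splits gave at least as many by construction (2 in the highest), which says nothing about chance.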

How the results depend on the processing

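The block without the first control siRNA hypoxia array was chosen after the results were seen, and the other alternatives before. Of the 276 calls of named genes 273 were kept with the replicate block, 271 with array weights, 268 with centring, 264 with quantile normalization again, 269 with a trended and robust prior, 275 with the mean of probes, 214 with all probes as features, 253 of 253 with dim genes left out and 127 of 157 with a contrast's own 6 arrays, and 2891 of 3312 in the leave-outs. Of 61 list calls 61 were kept with the block, 60 with centring, 51 with quantile normalization again, 44 with dim genes left out, 9 with an estimated correlation and 656 of 732 in the leave-outs. No result was called in the opposite direction, but 3 list calls were lost with a change of camera's direction. They were mitosis in the knockdown in hypoxia (0.727 without the first CtBP siRNA hypoxia array, leave-outs 4.43e-06 to 0.727), and in the interaction DNA replication (0.925 without the first control siRNA hypoxia array, 1.71e-06 to 0.925) and chaperones (0.925, 0.000159 to 0.925). In 4 more lost calls only the median changed sign, to -0.02 for glycolytic HIF targets and 0.02 for chaperones in the knockdown in hypoxia, -0.01 for epithelial genes in the interaction and 0.04 for DNA replication in the averaged knockdown. With the block DNA replication and mesenchymal genes newly passed in hypoxia with CtBP siRNA (adjusted p = 0.0356 each). In the hypoxia contrasts replicate numbers did not pair the arrays by the same check (r of 0.219, 0.218 and 0.081 with control siRNA, 0.098, 0.141 and 0.113 with CtBP siRNA), although 6 of 6 arrays correlated best with their own number in each, and the block gave 946 up and 2133 down, and 534 and 1035. The gene counts below moved by more than 1.5 times, and unless the alternative itself tests fewer arrays or sets a minimum change, the cause was not tested. Arrays give no depth, and dim genes near background limit what can be called.

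Knockdown in normoxia (2 up, 2 down) gave 40 and 12 with the block, 7 and 6 with centring, 10 and 5 with dim genes left out, 7 and 6 with the mean of probes, 0 and 0 with all probes, 13 and 8 with a trended prior, 45 and 21 with array weights, 8 and 9 with its own 6 arrays, 65 and 26 with the block without the first control siRNA hypoxia array, and 1 down with a minimum change. Leave-outs gave 1 to 18 up and 1 to 10 down.

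Knockdown in hypoxia (56 and 8) gave 203 and 41 with the block, 33 up with quantile normalization, 101 up with centring, 96 and 15 with dim genes left out, 1 and 0 with all probes, 15 down with array weights, 1 and 0 with its own 6 arrays, 9 and 1 with a minimum change and 33 and 4 with the block without that array. Leave-outs gave 6 to 239 up and 0 to 37 down.

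Hypoxia with control siRNA (718 and 1773) gave 437 and 1181 with its own 6 arrays and 128 and 253 with a minimum change, and leave-outs 416 to 820 up and 1101 to 2019 down. Hypoxia with CtBP siRNA (387 and 741) gave 619 and 1162 with array weights, 124 and 84 with a minimum change, and 727 and 1415 with the block without the first control siRNA hypoxia array, and leave-outs 200 to 553 up and 256 to 1096 down.

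The averaged knockdown (140 and 32) gave 287 and 77 with the block, 79 up with all probes, 239 and 70 with array weights, 10 and 1 with a minimum change and 244 and 82 with the block without that array, and leave-outs 61 to 240 up and 14 to 47 down. Averaged hypoxia (1207 and 2495) gave 1917 up with all probes and 126 and 149 with a minimum change, and leave-outs 907 to 1278 up and 2023 to 2695 down.

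Shared calls of the 2 knockdown contrasts (0 up, 1 down) were 30 and 4 with the block, 6 and 3 with dim genes left out and 0 down with a minimum change, with 0 to 3 and 0 to 1 in leave-outs. Shared hypoxia calls (263 and 607) were 82 and 62 with a minimum change, with 156 to 321 and 233 to 741 in leave-outs. Between the averages, 27 up in both became 50 with the block and 0 with a minimum change (10 to 29 in leave-outs), 7 down in both became 25, 12 with dim genes left out and 0 (3 to 17), 45 up with CtBP siRNA and down in hypoxia became 118, 68 with dim genes left out and 0 (20 to 116), and 7 down and up became 11 with the block and 0 (5 to 13).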

Other observations

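The histone and metallothionein groups and the test of stronger hypoxia in the dish of the first control siRNA hypoxia array were chosen after the results were seen, while the tests of the narrower intensity distribution and of the serum response factor targets were chosen before their results.

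Replication-dependent histone genes, whose transcripts are made in S phase for packing new DNA, formed a large falling group in hypoxia. Of 56 measured genes 35 fell and 1 rose with control siRNA, with a median of -0.98 and a range over leave-outs of -0.99 to -0.89 (camera p = 2.54e-22, and p = 0.00657 with an estimated correlation). With CtBP siRNA 27 fell, with a median of -0.56 and a range of -0.64 to -0.48 (camera p = 7.84e-20, and p = 0.00915 with an estimated correlation). H2BC14 (-3.24), H3C11 (-2.11), H4C3 (-1.65) and H1-2 (-1.58) fell with control siRNA, while H1-1, a dim gene (3.16 in normoxia), rose by 0.44. The difference between the siRNAs had a median of 0.24 (camera p = 1.82e-07, but p = 0.0865 with an estimated correlation). With arrays centred on their medians the medians were -1.06 and -0.60. Histone genes share sequence, so probes of paralogs can read each other's transcripts, and members are not independent. H2BC14, H3C11 and H2BC8 were among the largest falls seen before the group was chosen, and they stayed in it. The camera p-values of the group were not adjusted and may be too small for that reason.

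Metallothionein genes, which bind zinc and copper, were higher in averaged hypoxia. Of 9 measured, 5 rose with a median of 0.43 (camera p = 6.19e-05, but p = 0.0686 with an estimated correlation), and MT1X rose by 1.29 ± 0.30 with control siRNA (limma adjusted p = 0.0119). Members seen before the choice of this group were not set aside either, and its camera p-values were not adjusted.

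Among the 140 genes higher with CtBP siRNA in the averaged comparison, 8 genes, most of them of the actin cytoskeleton, were picked out by eye, with no test of enrichment. They were ACTA2 (1.05), CAV1 (1.02), ACTG2 (0.85), VCL (0.75), CSRP1 (0.74), TPM1 (0.69), PDLIM5 (0.65) and GSN (0.58). The pick held genes taken as targets of serum response factor, so it was not the full set of actin genes. LCP1 (1.33), which bundles actin, was not in it. The 8 genes had been seen before the test and are not independent evidence. A candidate explanation is higher activity of serum response factor, a transcription factor that drives such genes. Of 25 other textbook targets 23 were higher, with a median of 0.18 (camera p = 8.35e-07, and p = 0.0215 with an estimated correlation), and 1, LIMA1, passed over all genes (0.65 ± 0.12, adjusted p = 0.0154). The median lay between 0.17 and 0.26 over leave-outs, at 0.16 after quantile normalization and at 0.19 after centring. The result is consistent with that hypothesis, but the factor's activity was not measured and the small size may have other sources.

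The first control siRNA hypoxia array differed most from its group, with an SD of its deviation across genes of 0.248 against at most 0.19 for the others. A narrower intensity distribution fits, since its deviation fell with brightness with a Spearman rho of -0.303 across genes, where the lowest of the other arrays had -0.189. Its interquartile range was 2.67, against at least 2.89 on the others. Both values describe the same narrowing and are not separate evidence. Stronger hypoxia in that dish may also have contributed and stays open. The slope of its deviation on the hypoxia response measured with CtBP siRNA was 0.18, the highest of the 12 arrays. That slope was taken without removal of the trend with brightness, which may contribute to it. The array lay farthest along the first principal component (38.9), but also farthest out along the second (-32.4). On the other side, the HIF target lists deviated by a median of -0.29, the lowest of the 12 arrays. After removal of the trend with brightness their median was -0.18, close to the -0.14 of the lowest other array. Why the distribution was narrower was not tested.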
